A study of Mus musculus with 132 samples.

How the data were processed

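RNA was measured by sequencing of RiboTag immunoprecipitates (IP) and of whole-tissue inputs from mouse brain, 4 hours or 3 days after stroke or sham surgery, in females and males of a microglia line and an astrocyte line. Per the labels the microglia line was prepared with Smart-Seq2 and Nextera XT and the astrocyte line with NEBNext polyA kits, so the lines were fitted apart except for the difference of the stroke effect between them. According to the submitters' processing notes, reads were trimmed with Trim Galore 0.4.5 and cutadapt, checked with FastQC 0.11.7, aligned to mm10 (GRCm38.p6) with STAR 2.7.1 and quantified per gene with RSEM 1.3.1. The deposited files give for each gene the RSEM expected count, an estimate of the reads of the gene that is not scaled for depth or length. Per the file headers they also give TPM and FPKM. The deposited TPM, scaled by the authors' RSEM run to the same total in every library, and FPKM were not analysed here. The deposited length and effective length of each gene were used only to read the fragment length. The labels do not state the strand setting of the counts.

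The files list 54838 genes by Ensembl ID and symbol; 54723 IDs were found in the reference list of names, 54174 with the same symbol, and 204 symbols occur more than once. Of 132 libraries, 2 files stop before the value columns (microglia IP female stroke 3 days no. 110 and male stroke 3 days no. 98) and were left out. The sex label matched the Y-linked counts in 69 of 69 male and 61 of 61 female libraries. No pair of the 327 pairs of libraries within a group was a duplicate, the lowest chi-square per degree of freedom between counts being 7.46. The median share of genes with a count that was not whole was 7.28% in astrocyte IP and 5.96% in microglia IP libraries, and counts were rounded.

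Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr over the groups, robust quasi-likelihood fits) with 1 mean for each of the 8 groups of sex, time and treatment in a cell type, or 16 in the joint fit. The stroke effect at a time is the mean of the female and male contrasts; sex differences are female minus male, time differences 3 days minus 4 hours and cell type differences microglia minus astrocyte. IP was compared with input over the groups present. Inputs, with 1 or 2 libraries per sex, were fitted with time and treatment as groups and sex as a term. Genes passed at a Benjamini-Hochberg adjusted p of 0.05 over the genes tested. Gene levels are CPM, counts scaled to library size, with TMM factors. Tables were read with data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

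Gene lists were written before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternative settings described last. Response lists were homeostatic and disease-associated microglia, astrocyte homeostasis, pan-reactive, A1 and A2 astrocyte, extracellular matrix and scar, complement and phagocytosis, immediate early genes, type I interferon response, cytokines and chemokines, NF-kappaB targets, cell cycle, hypoxia and glycolysis, heat shock, unfolded protein response, cholesterol synthesis, antigen presentation and oxidative phosphorylation. Marker lists covered microglia, astrocytes, neurons, oligodendrocytes and their precursors, endothelial, mural and ependymal cells, fibroblasts, neutrophils, monocytes and border macrophages, and lymphocytes. Of the microglia markers 10 of 14, and of the astrocyte markers 12 of 13, are also in another list. In microglia 26 and in astrocytes 29 lists were tested per time with limma 3.58.1, using camera with a preset correlation of 0.01, then camera with the correlation estimated from the data, and fry. Adjusted p values are over the lists of a comparison; for genes, a second count is adjusted over the list alone.

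Named genes follow a fixed rule: for each stroke effect the 5 largest rises and 5 largest falls among called genes with an approved symbol, the same direction in both sexes and a mean log2 CPM of at least 3 in the higher group; the 2 members of each response list with the smallest p, or 4 where 8 or more were called; and for each marker list the most abundant member and the one with the smallest p. For differences the rule takes the 5 called genes with the smallest p, and for IP and inputs the marker lists and the 5 largest changes. Values of such a gene are also given where another comparison is described.

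The pipeline was tested on simulated data, with 200 genes changed by 1.5-, 2- or 4-fold in the real library sizes. Of 4-fold changes it recovered 75.8% in microglia and 97.0% in astrocytes at 3 days, 89.8% and 100.0% between IP and input, 71.2% and 92.4% for time differences, 69.2% for the cell type difference, 84.9% in astrocyte-line and 48.4% in microglia-line inputs. The last is under the limit of 60% set beforehand, at which work was to stop; after this was seen the limit was kept as a reported value only, because the 4-fold changes had a median ratio of estimated to simulated log2 fold change of 0.99. That ratio was 0.853 for 1.5-fold and 1.09 for 2-fold changes, so small changes in these inputs are poorly measured. False calls made up between 0 and 7.69% of calls, and contrasts with no simulated change gave 0 calls. Recovery of 2-fold changes was 63.6% in microglia and 81.8% in astrocytes at 3 days. It was 51.5% and 66.7% for time differences and 65.1% for the cell type difference. For 1.5-fold changes these values were 37.5%, 63.6%, 7.81%, 40.9% and 28.1%. Changes were simulated only at 3 days and between IP and input, so recovery at 4 hours and for sex differences was not measured. All other genes were simulated with 1 mean over the libraries of a fit. In the real data 13964 of 16147 genes differed between IP and input in the microglia line and 13994 of 16096 in the astrocyte line. The recovery and false call values therefore do not cover data in which most genes change, or batches.

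Library numbers that occur as IP and input had the same sex, treatment and time in 11 of 11 cases in the microglia line and 12 of 12 in the astrocyte line. After removal of the means of each time and treatment, with sex left in, IP and input of the same number were correlated over genes. The median r was 0.00747 in the microglia line, where 2 exceeded 0.1, and 0.148 in the astrocyte line, where 9 exceeded 0.1. Other numbers of the same time and treatment, in part of the other sex, gave medians of -0.00954 and -0.0217. A shared sex may therefore add to the correlation of the same number. The number was used as a block only as an alternative.

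Settings chosen before the data were examined were DESeq2 1.42.0 size factors, its Wald test, no low-count filter, voom with sample weights, only the libraries of a time, the neuron marker mean as a covariate, leaving out low-depth libraries, a separate variance per cell type, the replicate block, and leaving out each library of small groups in turn. Chosen after seeing the data were the library-number batch (478 and above against lower) as a term or within each range, leaving out 5 doubted IP libraries (microglia no. 91, 143, 153 and 251, astrocyte no. 527), and leaving out 5 microglia-line inputs that lay apart. The model counts were also compared with other splits of the same libraries. Results of some genes are withheld and not reported here, among them 1 library value counted among those far from their group.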

Results

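The series holds RNA sequencing libraries of mouse brain from RiboTag animals, in which a haemagglutinin-tagged ribosomal protein (Rpl22) is switched on in microglia (Cx3cr1-creERT2) or in astrocytes (Aldh1l1-creERT2), so that an immunoprecipitation (IP) of the tag pulls down the RNA on the ribosomes of that cell type. Animals had a distal occlusion of the middle cerebral artery (stroke) or a sham operation and were taken 4 hours or 3 days later. Input libraries came from the whole tissue before the IP. Of 132 libraries, 130 held values: 40 microglia IP, 64 astrocyte IP, 14 microglia-line input and 12 astrocyte-line input libraries. The microglia IP groups held 9 sham and 11 stroke libraries at 4 hours and 10 of each at 3 days. The astrocyte IP groups held 12 sham and 20 stroke libraries at 4 hours and 16 of each at 3 days. Total counts, in megacounts, ran from 1.95 to 34.4 in microglia IP libraries (median 21.5), from 8.25 to 29.2 in astrocyte IP libraries (median 18.4), from 19.7 to 30.7 in microglia-line inputs and from 20.3 to 30.4 in astrocyte-line inputs. Below, a change is the log2 fold change of stroke against sham, averaged over the sexes, with its standard error (SE). Levels are CPM, counts scaled to library size, as mean ± SD over libraries. Adjusted p values of genes are from edgeR and those of gene lists from limma's camera. A list count in brackets as adjusted over the list alone uses p values adjusted over its members. The astrocyte libraries carry numbers in a lower and a higher range (478 and above), a possible batch that the labels do not name and that was noticed after the data were examined. In astrocyte IP libraries the fragment length ran from 204.8 nt (no. 202) to 264.3 nt (no. 161) in the lower range. In the higher range it ran from 263.6 nt (no. 484) to 295.7 nt (no. 497). The IP libraries thus differed technically between the ranges, while the fragment lengths of the inputs overlapped. For lists called by camera in all astrocyte libraries, and for some others, medians within each range (within batches) stand beside the pooled ones, the higher range first. Other astrocyte values are pooled over the ranges unless stated. At 3 days each IP group of sex and treatment held 2 higher-numbered and 6 lower-numbered libraries. At 4 hours the ranges were not balanced over treatment. Female sham held 3 and 1, female stroke 4 and 6, male sham 4 and 4, and male stroke 4 and 6. Pooled values at 4 hours may therefore carry part of a difference between the ranges.

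Comparing IP with input asked how far each pulldown was enriched for its cell type. In the microglia IP all 14 microglia markers were enriched over the input, with a median log2 ratio of 6.77. C1qa, a chain of complement C1q, was enriched by 7.28 (SE 0.20), the microglial Fc receptor-like gene Fcrls by 7.23 (SE 0.17), the integrin Itgax by 7.43 (SE 0.34), and Lag3 and Cd180 by 7.21 and 7.16. Neuron markers were depleted in 14 of 14 (median -3.36), oligodendrocyte markers in 10 of 10 (median -3.69) and astrocyte markers in 12 of 13 (median -2.87). The exception was the glutamine synthetase gene Glul, enriched by 0.73. Of the monocyte and border macrophage markers, 9 of 10 were enriched (median 5.85). Their mean log2 CPM plus 1 in sham IP libraries at 3 days was 4.14, beside 11.22 for the microglia markers. The pulldown thus cannot be taken as RNA of microglia alone. Below, a stroke effect in microglia is one in the microglia IP. The endothelial marker Pecam1 was enriched by 1.62 while 8 of the 10 endothelial markers were depleted. Mural cell (8 of 8), fibroblast (6 of 6) and ependymal (4 of 4) markers were depleted, oligodendrocyte precursor markers in 5 of 6. Both measured neutrophil markers were enriched, and of the 2 measured lymphocyte markers 1 was enriched and 1 depleted.

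In the astrocyte IP all 13 astrocyte markers were enriched (median 3.54). By contrast 14 of 14 neuron markers (median -4.06), 10 of 10 endothelial markers (median -3.20) and 13 of 14 microglia markers (median -2.33) were depleted. These ratios pool sham and stroke libraries of both times. At 3 days the mean log2 CPM plus 1 of the microglia markers was 2.43 in IP and 4.53 in input after sham. After stroke it was 5.36 and 6.51. As a share of the input level after stroke, the rise in the IP ran from 5.90% (P2ry12) to 220% (Ctss). The largest change was the depletion of a mitochondrial transcript, mt-Nd4l, by -5.25 (SE 0.42), whose call was lost with the DESeq2 Wald test. Neuronal transcripts followed, the potassium channel gene Kcna1 by -4.80 (SE 0.18), the pentraxin Nptx1 by -4.79 (SE 0.17), the dynamin Dnm1 by -4.78 (SE 0.19) and the chloride transporter Slc12a5 by -4.73 (SE 0.17). Oligodendrocyte markers were depleted in 9 of 10 (median -3.77) and precursor markers in 6 of 6 (median -3.22). Some markers of other cells were higher in the astrocyte IP than in the input. These were 6 of 8 neutrophil markers (1 lower, median 3.74) and 5 of 6 ependymal and choroid plexus markers (median 1.39). So were 6 of 11 monocyte and border macrophage markers (3 lower, median 1.35) and 3 of 6 fibroblast markers (median 0.66). Mural cell markers were higher in 2 of 8 and lower in 4 (median -1.13), and lymphocyte markers higher in 1 of 3 and lower in 2 (median -2.78). Across all genes 13964 of 16147 differed between IP and input in the microglia line and 13994 of 16096 in the astrocyte line. With replicate number as a block, the counts were 11973 and 13073. DESeq2 size factors moved the median log2 ratio of all genes in the microglia line from -0.03 to -0.30, a shift small beside the marker values.

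**Figure D1:**
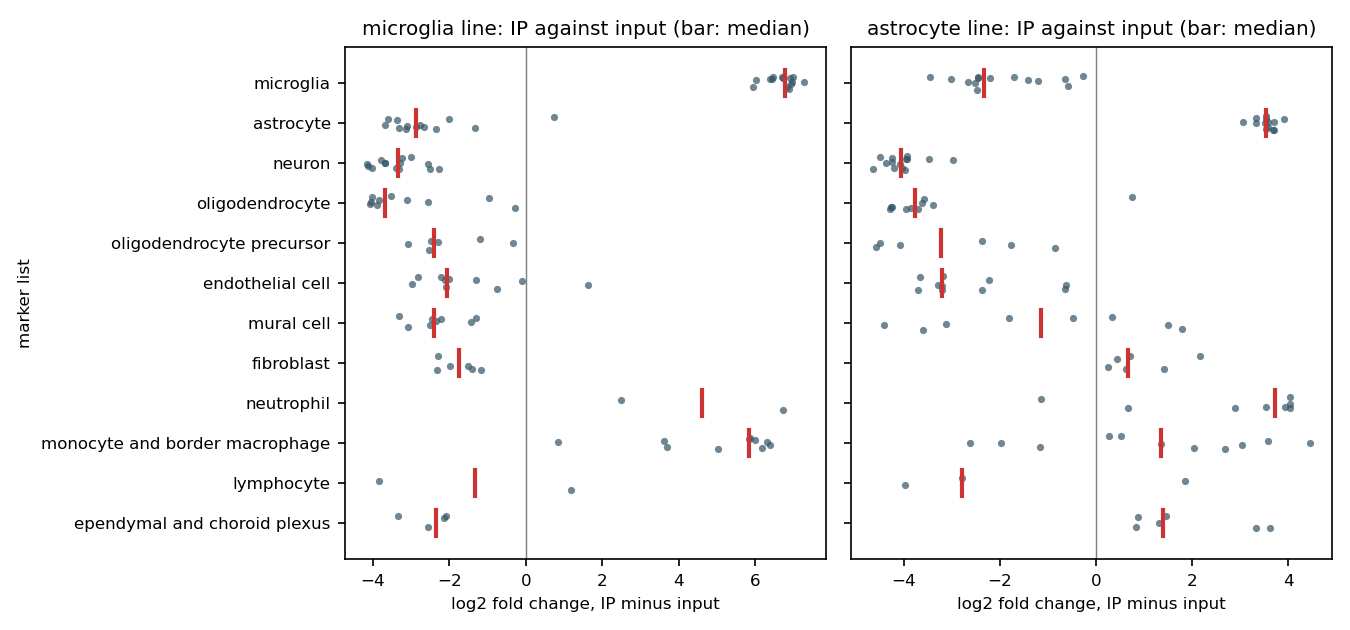
Log2 ratio of IP to input for each measured member of the cell marker lists, in the microglia line and in the astrocyte line. Each point is a gene and the bar is the median of the list. Microglia markers sit at a median of 6.77 in the microglia line and -2.33 in the astrocyte line, and astrocyte markers at -2.87 and 3.54.

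The stroke effect in microglia at 4 hours was a rise of early response, cytokine, heat shock and glycolysis genes. Immediate early genes, transcription factors induced within minutes to hours of a stimulus, rose in 18 of 20 (19 adjusted over the list alone, median 2.14). Atf3, a stress-induced repressor and activator, went from 13.7 ± 4.54 CPM in 9 sham libraries to 230.0 ± 144.8 in 11 stroke libraries (4.06, SE 0.33). Egr2 went from 1.66 ± 0.631 to 29.5 ± 18.03 CPM, and Egr1 and Fos rose by 3.05 and 3.61. Cytokine and chemokine genes rose in 15 of 18 (15 adjusted over the list alone, median 2.62). Csf1, a growth factor of microglia, went from 11.3 ± 2.94 to 159.0 ± 61.4 CPM (3.81, SE 0.27). The chemokines Ccl3 and Ccl4 went from 15.2 ± 7.67 to 271.5 ± 161.5 CPM and from 17.7 ± 8.74 to 332.6 ± 208.9 CPM, and oncostatin M (Osm) rose by 2.69 (SE 0.29). Heat shock genes, coding for chaperones, rose in 12 of 13 (12 adjusted over the list alone, median 1.03). The inducible chaperone Hspa1a went from 19.8 ± 14.8 to 1303 ± 1182 CPM (6.03, SE 0.63). Its near-identical paralog Hspa1b rose by 5.97, and the split of reads between the pair is uncertain. The small chaperone Hspb1 rose by 5.36 (SE 0.59), Hsph1 by 1.92 and the co-chaperone Bag3 by 1.95.

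Hypoxia and glycolysis genes rose in 12 of 17 (13 up and 1 down adjusted over the list alone, median 0.88). The glucose transporter Slc2a1 went from 76.5 ± 15.1 to 277.2 ± 61.8 CPM (1.88, SE 0.15). The glycolytic regulator Pfkfb3 rose by 1.54 (SE 0.15), lactate dehydrogenase Ldha by 1.06 and phosphoglycerate kinase Pgk1 by 0.88. NF-kappaB targets rose in 9 of 15 (11 up and 1 down adjusted over the list alone, median 1.03). Nfkbiz was at 2.40, Nfkb2 at 1.43, Tnfaip3 at 1.18 and Icam1 at 1.03. These 5 lists held with an estimated correlation (adjusted p 0.00085, 0.00314, 0.000877, 0.000228 and 0.00579 in the order given). Gdf15, a stress-induced cytokine outside the lists, rose by 5.08 (SE 0.53).

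Homeostatic microglia genes, expressed by surveying microglia, fell in 8 of 18 (9 adjusted over the list alone, median -0.35, camera adjusted p 7.46e-06, adjusted p = 0.183 with an estimated correlation). Tmem119 went from 3503 ± 602.2 to 2034 ± 460.1 CPM (-0.78, SE 0.13) and the purinergic receptor P2ry12 from 2103 ± 473.7 to 1383 ± 289.7 CPM (-0.60, SE 0.18). The transcription factor Sall1 changed by -0.62 and Selplg by -0.60. Disease-associated microglia genes rose in 9 of 18 (9 adjusted over the list alone, median 0.53, adjusted p = 0.358 with an estimated correlation). Lipoprotein lipase Lpl rose by 2.35, galectin-3 (Lgals3) by 2.34, Cd63 by 0.95 and Cd9 by 0.72. Unfolded protein response genes rose in 6 of 15 (7 adjusted over the list alone, median 0.46, adjusted p = 0.182 with an estimated correlation). Trib3 was at 3.41 and Sesn2 at 1.17. The largest falls were those of Thrsp (-1.17, SE 0.20), the lectin Clec4a2 (-1.13, SE 0.17), Inka1 (-1.08), the transporter Slc46a3 (-1.05) and Plxna4os1 (-1.29). Plxna4os1 is an antisense transcript, and its value is uncertain because the strand setting of the counts is not stated.

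Other lists were not called as groups at 4 hours in microglia: complement and phagocytosis (4 of 17 up, with the lipopolysaccharide co-receptor Cd14 at 2.35 and the C3a receptor C3ar1 at 1.19), type I interferon response (2 of 20 up, Rsad2 1.70 and Cxcl10 1.69), cholesterol synthesis (6 of 18 up). The same held for cell cycle (1 of 20 down, the replication factor Mcm3 at -0.50), antigen presentation (2 of 15 down, with the immunoproteasome subunit Psmb9 at -0.72) and oxidative phosphorylation (0 of 17 past the threshold by edgeR). Marker lists of other cells had medians of 0.08 (neuron), 0.14 (astrocyte), 0.06 (oligodendrocyte), 0.08 (oligodendrocyte precursor), -0.21 (endothelial), -0.20 (mural), 0.05 (fibroblast), 0.01 (monocyte), -0.81 (lymphocyte), 0.14 (ependymal) and 1.49 (neutrophil). None passed the camera threshold, while fry called the neutrophil list up (adjusted p = 0.0308) and the lymphocyte list down (adjusted p = 0.00637). Of their members, 1 neutrophil and 1 monocyte marker were up and 1 astrocyte marker down by edgeR. The microglia markers themselves had 1 member up and 2 down of 14 (median -0.20, camera adjusted p 0.0118, adjusted p = 0.501 with an estimated correlation). For the antigen presentation, oligodendrocyte and ependymal lists the camera direction was down while median and mean were above 0. In all, edgeR called 2158 of 16561 genes (1288 higher, 870 lower), 444 of them over 2-fold higher and 56 over 2-fold lower. Voom with sample weights (limma) called 3654.

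**Figure D2:**
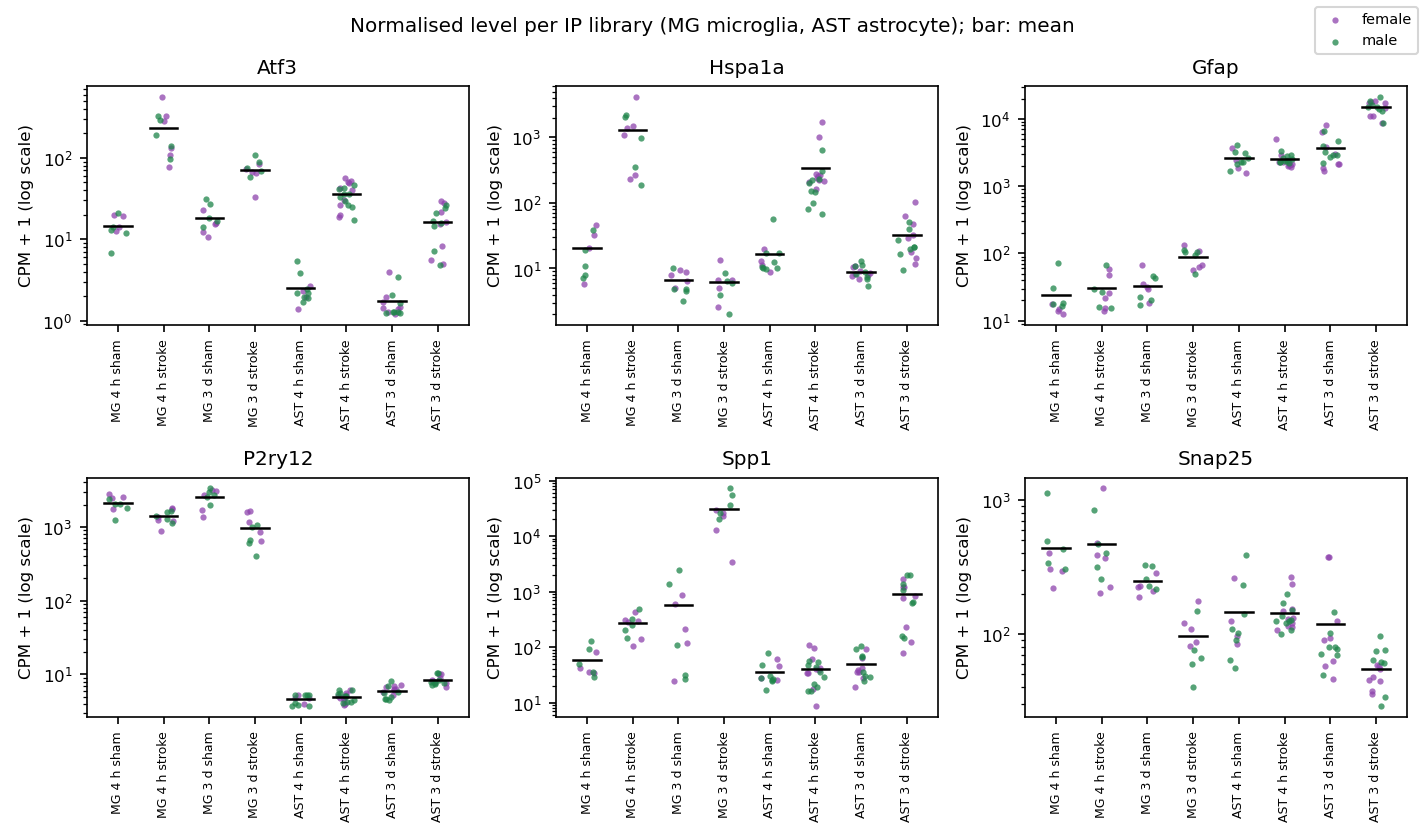
CPM plus 1 on a log scale of 6 genes in every IP library of both cell types, by time and treatment. Points are libraries, purple for female and green for male, and the bar is the mean. Mean Hspa1a in microglia at 4 hours is 19.8 CPM in sham and 1303 CPM in stroke libraries, and mean Gfap in astrocytes at 3 days 3658 and 14850 CPM.

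By 3 days the stroke effect in microglia covered interferon, proliferation and disease-associated genes. All 20 type I interferon response genes rose (20 adjusted over the list alone, median 2.72, adjusted p = 0.0323 with an estimated correlation). Stat2, a signal transducer, rose by 2.03 (SE 0.22), the RNA sensor Ifih1 by 1.70 (SE 0.16) and Xaf1 by 2.26 (SE 0.24). All 20 cell cycle genes rose (20 adjusted over the list alone, median 1.71, adjusted p = 0.0544 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 went from 15.8 ± 15.1 to 83.0 ± 35.3 CPM, and Mcm6 rose by 1.71, the DNA clamp Pcna by 1.41 and thymidylate synthase Tyms by 1.38. Disease-associated microglia genes rose in 15 of 18 (15 adjusted over the list alone, median 1.95, adjusted p = 0.0323 with an estimated correlation). Osteopontin (Spp1) went from 574.4 ± 782.9 to 30180 ± 19890 CPM (5.72, SE 0.72). The receptor kinase Axl rose by 2.60, cystatin F (Cst7) by 2.62, Cd63 by 2.05 and cathepsin B (Ctsb) by 1.78. Homeostatic genes fell in 16 of 18 (16 adjusted over the list alone, median -0.90, adjusted p = 0.0544 with an estimated correlation). P2ry12 went from 2541 ± 658.7 to 958.3 ± 406.8 CPM (-1.44, SE 0.18). The lectin Siglech changed by -1.32, Selplg by -0.997 and the growth factor receptor Csf1r by -0.91.

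Cytokine genes were 12 up and 1 down of 18 (12 up and 2 down adjusted over the list alone, median 2.07, adjusted p = 0.219 with an estimated correlation). Ccl4 was at 3.26, Ccl3 at 2.58, Csf1 at 2.16 and Cxcl16 at 1.70. Hypoxia and glycolysis genes rose in 10 of 17 (10 adjusted over the list alone, median 0.61, adjusted p = 0.0544 with an estimated correlation). Ldha rose by 1.71, Pgk1 by 1.304 and Eno1 by 0.94. Oxidative phosphorylation genes rose in 13 of 17 (13 adjusted over the list alone, median 0.42, adjusted p = 0.241 with an estimated correlation). Cox5a rose by 1.10 and Ndufb8 by 0.87. Antigen presentation genes moved both ways, 8 up and 4 down of 15 (9 and 5 adjusted over the list alone, median 0.56, adjusted p = 0.363 with an estimated correlation). The peptide transporter Tap1 rose by 1.81, Psmb9 by 1.12 and Psmb8 by 1.012. H2-K1 was at 1.56, uncertain because it is one of a paralog family. Complement and phagocytosis genes were 8 up and 2 down of 17 (9 and 3 adjusted over the list alone, median 0.26, adjusted p = 0.311 with an estimated correlation). C3ar1 was at 1.17, the lysosomal protein Cd68 at 1.06 and Gas6 at 0.96. Unfolded protein response genes were 8 up and 1 down of 15 (8 and 1 adjusted over the list alone, median 0.64, adjusted p = 0.305 with an estimated correlation). Trib3 was at 2.92 and Sdf2l1 at 1.15.

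Outside the lists, the serotonin receptor Htr2b went from 1.15 ± 1.46 to 44.0 ± 25.9 CPM (5.13, SE 0.55) and the cholesterol hydroxylase Ch25h from 5.70 ± 6.57 to 141.6 ± 48.4 CPM (4.55, SE 0.59). By contrast the prostaglandin receptor Ptger3 fell by 2.71, the lectin Cd209a by 2.80, Ccdc162 by 3.11 and the transcription factor Mycl by 2.57. Cspg4, coding for the NG2 proteoglycan and listed as an oligodendrocyte precursor marker, rose by 4.04 (SE 0.34), from 3.57 ± 1.82 to 58.1 ± 20.8 CPM. The other 5 measured markers of that list did not pass. Neuron markers fell in 13 of 14 beside these groups (14 adjusted over the list alone, median -1.25, adjusted p = 0.307 with an estimated correlation). Snap25 went from 246.4 ± 47.0 to 95.4 ± 42.5 CPM. Other marker lists were not called: microglia (3 up and 5 down of 14), astrocyte (1 up and 6 down of 13), oligodendrocyte (1 up of 10), endothelial (4 down of 10) and mural (3 down of 8). Nor were fibroblast (0 of 6 by edgeR), neutrophil (2 up and 1 down of 6), lymphocyte (1 up of 3), ependymal (1 down of 4) or monocyte and border macrophage markers (5 up and 4 down of 11, median -0.21 with a mean of 1.16 and a camera direction of up). The oligodendrocyte precursor list too had a median below 0 (-0.26) and a mean above it (0.25). Immediate early genes (1 up, Atf3 at 2.05, and 7 down of 20), NF-kappaB targets (5 up and 2 down of 15), heat shock (2 of 13 up) and cholesterol synthesis (2 of 18 down) were not called either. The edgeR fit called 6515 of 16561 genes, 3259 higher and 3256 lower. With the mean of the neuron markers as a covariate 3195 were called, and Snap25 was no longer among them. With it the neuron, complement and unfolded protein response lists were no longer called (medians 0.11, 0.04 and 0.29), while the microglia list was called down (-0.21) and the astrocyte (0.33), oligodendrocyte (0.56) and oligodendrocyte precursor lists (0.58) up. The covariate is built from the neuron list itself.

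The stroke effect in astrocytes at 4 hours was an early response with heat shock and unfolded protein genes. Immediate early genes rose in 18 of 20 (19 adjusted over the list alone, median 1.77, and 1.67 and 2.10 within the higher-numbered and lower-numbered libraries). Atf3 went from 1.49 ± 1.10 CPM in 12 sham libraries to 34.9 ± 11.7 in 20 stroke libraries (4.69, SE 0.41) and Fos from 25.7 ± 17.99 to 207.5 ± 92.8 CPM (3.24, SE 0.29). Fosl2 rose by 2.44, and Jun went from 63.5 ± 17.3 to 263.4 ± 100.5 CPM (2.09, SE 0.18). Heat shock genes rose in 9 of 13 (11 adjusted over the list alone, median 0.63, within batches 0.17 and 0.67). Hspa1a went from 15.4 ± 13.2 to 335.2 ± 387.3 CPM (4.44, SE 0.45). Hspa1b rose by 4.12 with the same uncertainty between paralogs, Hsph1 by 1.303 and Bag3 by 1.15. Unfolded protein response genes rose in 7 of 15 (9 adjusted over the list alone, median 0.35, within batches 0.45 and 0.40). The glutathione-degrading enzyme Chac1 rose by 3.29 (SE 0.37) and Sesn2 by 0.84. These 3 lists held with an estimated correlation (adjusted p 1.24e-05, 0.00417 and 0.001).

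Several reactive astrocyte and immune lists were called by camera with its preset correlation and lost with an estimated one. A2 astrocyte genes rose in 7 of 12 (8 adjusted over the list alone, median 1.34, within batches 1.17 and 1.68, adjusted p = 0.0786 with an estimated correlation). Cd14 was at 2.25 and Slc10a6 at 2.07. Pan-reactive genes rose in 6 of 13 (8 adjusted over the list alone, median 1.03, within batches 0.78 and 1.33, adjusted p = 0.161 with an estimated correlation). Hspb1 went from 5.602 ± 2.59 to 20.8 ± 9.69 CPM and the oncostatin receptor Osmr rising by 1.27. Cytokine genes rose in 11 of 19 (14 adjusted over the list alone, median 1.48, within batches 0.92 and 2.54, adjusted p = 0.112 with an estimated correlation). NF-kappaB targets rose in 7 of 15 (8 adjusted over the list alone, median 0.36, within batches 0.37 and 0.25, adjusted p = 0.0817 with an estimated correlation), with Nfkbiz at 1.04. Interferon response genes rose in 6 of 20 (10 adjusted over the list alone, median 0.46, within batches 0.46 and 0.48, adjusted p = 0.223 with an estimated correlation), with Irf9 at 0.66. A1 astrocyte genes (3 of 11 up, median 0.50, adjusted p = 0.386 with an estimated correlation) and extracellular matrix genes (5 of 20 up, median 0.18, adjusted p = 0.386 with an estimated correlation) had few members called. Within batches these medians were 0.41 and 0.63 (A1) and 0.21 and 0.06 (extracellular matrix), and neither list was called in the lower range. Few members were also called of complement genes (3 of 17 up, median 0.73, adjusted p = 0.451 with an estimated correlation), antigen presentation genes (1 of 15 up, median 0.50, adjusted p = 0.591 with an estimated correlation) and cell cycle genes (0 of 20 past the edgeR threshold, median 0.58, adjusted p = 0.641 with an estimated correlation). Within batches the medians were 0.66 and 0.92 (complement), 0.41 and 0.54 (antigen presentation) and 0.05 and 0.52 (cell cycle). Complement and antigen presentation were not called in the lower range, and cell cycle in neither. Astrocyte homeostasis genes fell in 3 of 18 (median -0.10, within batches 0.01 and -0.30, the former not called, adjusted p = 0.386 with an estimated correlation). Among them were the amino acid transporter Slc7a10 (-0.61) and Fgfr3 (-0.44), neither past the threshold in the higher-numbered libraries. Of 17 oxidative phosphorylation genes 1 fell (median -0.19, within batches -0.12 and -0.12, adjusted p = 0.217 with an estimated correlation). Hypoxia (4 of 17 up, with the vasodilator peptide adrenomedullin, Adm, at 1.68) and cholesterol synthesis (2 of 18 up) were not called in all libraries (medians 0.13 and 0.07). Both were called up in the higher-numbered libraries alone (within batches 0.14 and 0.08 for hypoxia, 0.17 and 0.04 for cholesterol synthesis). The glycosyltransferase Galnt18 fell by 0.87 (SE 0.14), and the Notch effector Hes5 by 0.96 (SE 0.19) but not in the higher-numbered libraries alone.

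Markers of other cells moved beside these groups in the astrocyte IP at 4 hours. Neutrophil markers rose in 7 of 9 (8 adjusted over the list alone, median 1.95, within batches 2.31 and 1.62, adjusted p = 0.178 with an estimated correlation). S100a9 went from 5.09 ± 3.27 to 20.3 ± 30.95 CPM but passed within neither batch. Male stroke library 481 lay far above its group in the neutrophil markers. Their mean log2 CPM plus 1 was 4.10 there against a median of 1.78 in the others. Monocyte markers rose in 4 of 11 (median 0.43, within batches 0.65 and 1.08, the latter not called, adjusted p = 0.451 with an estimated correlation). Astrocyte markers had 3 of 13 lower (median -0.10, within batches 0.01 and -0.25, the former not called, adjusted p = 0.395 with an estimated correlation). Markers of microglia (1 of 14 up, median 0.10), neurons (median 0.02), oligodendrocytes (0.11), their precursors (-0.18), endothelial cells (0.04, with a mean of -0.03), mural cells (-0.05), fibroblasts (-0.03), lymphocytes (0.43) and ependymal cells (0.93) were not called. Within batches the neuron median was -0.37 in the higher-numbered and 0.68 in the lower-numbered libraries, the oligodendrocyte median -0.16 and 0.73 and the ependymal median -0.16 and 2.06. All 3 lists were called up in the lower-numbered libraries alone. The edgeR fit called 1486 of 16098 genes (1021 higher, 465 lower). It called 518 in the higher-numbered libraries, 434 in the lower-numbered libraries, where the female sham group holds 1 library, and 1750 with the batch as a term. Voom with sample weights called 4963 (2187 higher, 2776 lower), and without female sham library 491 the count was 918.

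In the astrocyte IP at 3 days reactive, immune and proliferation genes were higher and homeostatic and cholesterol synthesis genes lower. Microglia (median 3.96) and monocyte (median 3.77) markers rose in the same libraries. All 13 pan-reactive genes rose (13 adjusted over the list alone, median 2.60, within batches 4.00 and 2.34). The intermediate filament genes Gfap and Vim went from 3658 ± 1915 to 14850 ± 3577 CPM (2.04, SE 0.18, 16 libraries each) and from 189.8 ± 118.0 to 1629 ± 599.1 CPM (3.12, SE 0.21). The hyaluronan receptor Cd44 rose by 2.54 and Hspb1 by 3.42. A1 genes were 9 up and 1 down of 11 (9 and 1 adjusted over the list alone, median 2.20, within batches 2.59 and 2.04). Srgn was at 3.61 and Ggta1 at 1.78. A2 genes rose in 11 of 12 (11 adjusted over the list alone, median 2.93, within batches 3.30 and 2.79), with Emp1 at 4.24, Tm4sf1 at 3.90 and S100a10 at 2.11. All 20 interferon response genes rose (20 adjusted over the list alone, median 2.33, within batches 2.62 and 2.19), with Oasl2 at 2.63 and Ifitm3 going from 22.8 ± 7.36 to 127.6 ± 59.7 CPM. Cholesterol synthesis genes fell in 17 of 18 (17 adjusted over the list alone, median -0.77, within batches -0.79 and -0.78). Squalene epoxidase Sqle went from 214.0 ± 19.95 to 118.3 ± 26.1 CPM (-0.84, SE 0.09). Squalene synthase Fdft1 changed by -0.80, Dhcr7 by -0.80 and Msmo1 by -0.77. These lists held with an estimated correlation (adjusted p 0.0198 for the first 4 and 0.0238 for cholesterol synthesis).

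Astrocyte homeostasis genes fell in 14 of 18 (16 adjusted over the list alone, median -0.47, within batches -0.50 and -0.48, adjusted p = 0.116 with an estimated correlation). Glutamine synthetase Glul went from 20370 ± 2710 to 13020 ± 2898 CPM (-0.63, SE 0.09). The growth factor receptor Fgfr3 changed by -0.72, the glycolytic aldolase Aldoc by -0.57 and Acsbg1 by -0.54. All 20 cell cycle genes rose (20 adjusted over the list alone, median 2.68 beside 3.18 in the whole-tissue inputs, within batches 3.26 and 2.56, adjusted p = 0.0542 with an estimated correlation). Rrm2 went from 11.1 ± 7.79 to 66.7 ± 24.5 CPM and Mcm2 rose by 2.02. The nephrin-like adhesion gene Kirrel2 fell by 1.23 (SE 0.14) and the phospholyase Etnppl by 1.21 (SE 0.23). In the extracellular matrix list 9 were up and 5 down of 20 (median 0.18, not called), with thrombospondin Thbs1 at 5.48 and Tgfbi at 5.54. NF-kappaB targets were 12 up and 2 down of 15 (median 0.75, within batches 1.03 and 0.63, adjusted p = 0.0622 with an estimated correlation). Immediate early genes were 10 up and 5 down of 20 (median 0.55, within batches 0.21 and 0.73, the former not called, adjusted p = 0.561 with an estimated correlation) and unfolded protein response genes 10 up and 2 down of 15 (median 0.51, within batches 0.39 and 0.44, adjusted p = 0.31 with an estimated correlation). Hypoxia (5 up and 5 down of 17), heat shock (6 up and 1 down of 13) and oxidative phosphorylation (5 down of 17) were not called in all libraries. Heat shock was called up in the higher range alone (within batches 0.32 and 0.22) and oxidative phosphorylation down in the lower range alone (within batches -0.05 and -0.14).

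Lists of immune genes rose in the astrocyte IP at 3 days together with the markers of microglia and monocytes. All 14 microglia markers were higher (14 adjusted over the list alone, median 3.96, within batches 4.21 and 3.83, adjusted p = 0.0334 with an estimated correlation). The protease Ctss went from 15.2 ± 19.5 to 457.0 ± 354.7 CPM (4.92, SE 0.42). All 11 monocyte and border macrophage markers were higher (11 adjusted over the list alone, median 3.77, within batches 4.05 and 3.56, adjusted p = 0.0573 with an estimated correlation). Arginase Arg1 went from 1.83 ± 3.16 to 96.4 ± 81.2 CPM (5.73, SE 0.50). Complement and phagocytosis genes were 14 up and 3 down of 17 (14 and 3 adjusted over the list alone, median 4.05, within batches 4.35 and 3.99, adjusted p = 0.0238 with an estimated correlation). Cd68 was at 5.09, C3ar1 at 4.996 and C1qb at 4.58. Antigen presentation genes rose in 15 of 15 (15 adjusted over the list alone, median 2.71, within batches 2.86 and 2.60, adjusted p = 0.0352 with an estimated correlation). Psmb8 was at 3.10 and Tap1 at 1.85. Cytokine genes rose in 19 of 19 (19 adjusted over the list alone, median 3.60, within batches 4.65 and 3.46, adjusted p = 0.0546 with an estimated correlation), with the chemokine Ccl2 at 4.64 and Cxcl16 at 3.77. The macrophage scavenger receptor Msr1, Adam8 and Lat2 rose by 5.56, 5.56 and 5.61. Neutrophil markers rose in 7 of 9 (median 2.05, within batches 1.998 and 2.09, adjusted p = 0.31 with an estimated correlation).

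Neuron markers fell in 12 of 14 in these libraries (median -0.83, within batches -1.38 and -0.37, the latter not called, adjusted p = 0.561 with an estimated correlation). Snap25 went from 117.9 ± 103.7 to 53.9 ± 17.96 CPM. Among the sham libraries it was at 373.2 and 376.9 CPM in female no. 523 and 530, both in the higher range. In the other sham libraries it was at most 145.4 CPM (male no. 368). How much of the fall of the neuron markers rests on no. 523 and 530 was not tested. Astrocyte markers were 1 up (Gfap) and 9 down of 13 (median -0.50, within batches -0.57 and -0.49, the former not called, adjusted p = 0.257 with an estimated correlation). Oligodendrocyte (1 up of 10), oligodendrocyte precursor (0 of 6 by edgeR) and endothelial (3 up of 10) markers were not called as lists. Nor were fibroblast (5 up of 6, called up in the higher-numbered libraries alone with a median of 1.24), ependymal (4 up of 6), mural (1 up and 1 down of 6, median 0.10 with a camera direction of down) or lymphocyte (0 of 3 by edgeR, median -0.15 with a mean of 0.10) markers. The edgeR fit called 8102 of 16098 genes (4173 higher, 3929 lower), 1851 over 2-fold higher and 118 over 2-fold lower. It called 6466 in the higher-numbered and 7843 in the lower-numbered libraries, and 9373 with the batch as a term.

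**Figure D3:**
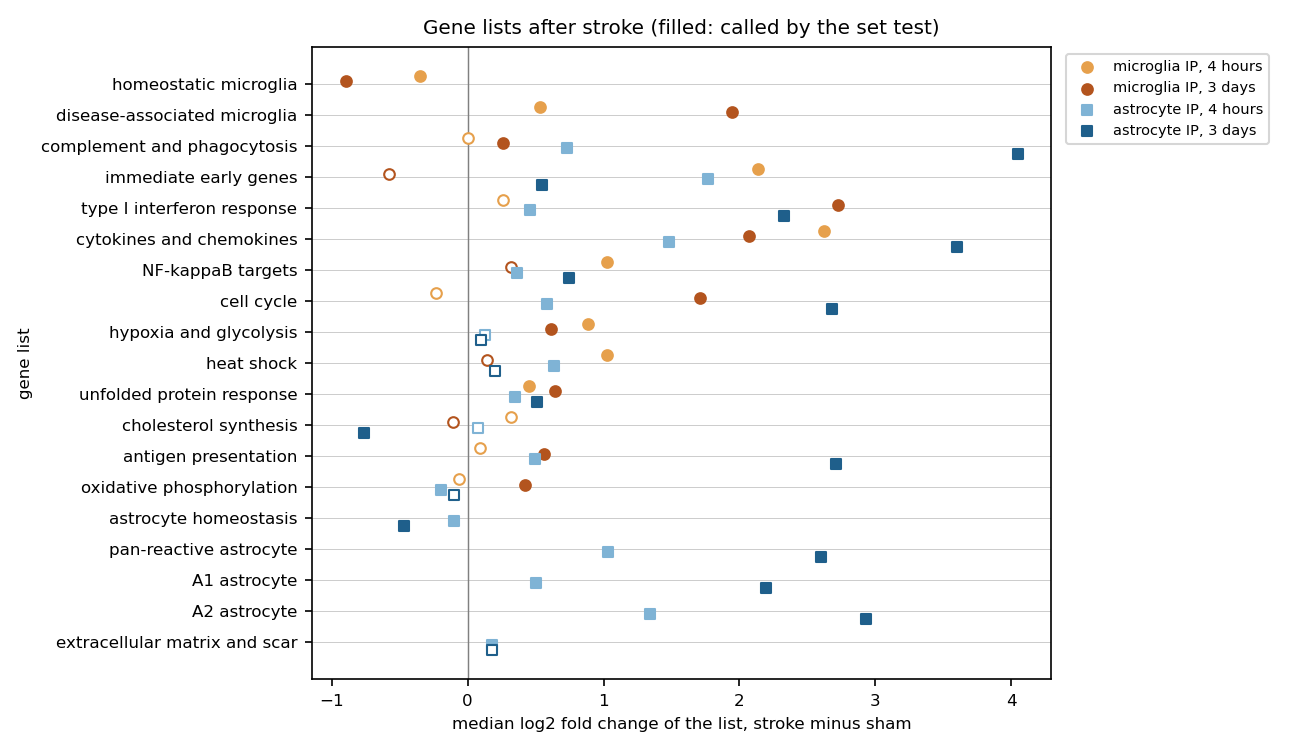
Median log2 fold change of stroke against sham over the measured members of each response list, for microglia and astrocyte IP libraries at 4 hours and 3 days. Immediate early genes sit at 2.14 in microglia and 1.77 in astrocytes at 4 hours, and interferon response genes at 2.72 and 2.33 at 3 days.

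Whether the stroke effect differed between females and males was tested as the difference of the 2 effects (female minus male). In microglia edgeR called 0 genes at 4 hours (1073 at an unadjusted p under 0.05; DESeq2 2, voom 0) and 0 at 3 days (1682 at an unadjusted p under 0.05; DESeq2 17, voom 34). In astrocytes it called 0 at 3 days (1277 at an unadjusted p under 0.05; DESeq2 3, voom 89) and 2 at 4 hours, both with the lower value in females. Des, coding for the intermediate filament desmin of muscle and mural cells, had a difference of -3.19 (SE 0.56), with -3.05 in females and 0.14 in males. Gm26917, a gene without an approved symbol that was named after its values were seen, had a difference of -5.60, with -4.59 in females and a value above 0 in males. Both calls were lost in the higher-numbered and in the lower-numbered libraries and with voom, each of which called 0, and DESeq2 called 1 gene. Within each sex 1145 genes (female) and 666 (male) passed in microglia at 4 hours, 1628 and 5763 at 3 days, and in astrocytes 254 and 472 at 4 hours and 5128 and 5970 at 3 days. Such counts do not test a difference between the sexes. Across genes, female and male effects correlated with a Pearson r of 0.33 and 0.57 in microglia and 0.61 and 0.87 in astrocytes, genes not being independent replicates.

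The change of the stroke effect from 4 hours to 3 days was tested within each cell type (3 days minus 4 hours). In microglia several of the genes with the smallest p turned from lower at 4 hours to higher at 3 days. The immunoproteasome subunit Psmb9 went from -0.72 to 1.12 (difference 1.83, SE 0.20), the ISG15-activating enzyme Uba7 from -0.42 to 1.24 (difference 1.66, SE 0.18) and the telomerase-associated gene Tep1 from -0.76 to 0.996 (difference 1.75, SE 0.18). H2-T22, of a paralog family, differed by 2.13. Errfi1, a feedback inhibitor of epidermal growth factor receptors, went the other way, from 1.08 to -0.62 (difference -1.70, SE 0.17). In astrocytes the transmembrane glycoprotein Gpnmb differed by 4.01 (0.48 at 4 hours and 4.49 at 3 days), Tedc1 by 2.89, AI506816 by 2.26, Dhrs1 by 2.09 and Nap1l5 by -1.05, from 0.29 to -0.76. Gpnmb is also in the disease-associated microglia list. Microglia (median 3.96) and monocyte (median 3.77) markers rose in the same astrocyte IP libraries at 3 days. What RNA of immune cells adds to the time differences in astrocytes was not tested. The test called 4269 of 16561 genes in microglia (2174 higher and 2095 lower at 3 days) and 4926 of 16098 in astrocytes (2826 and 2100). Voom called 6504 and 8523, and in astrocytes the within-batch counts were 4095 in the higher-numbered and 1860 in the lower-numbered libraries. Of the genes higher at 4 hours, 554 of 1288 in microglia and 546 of 1021 in astrocytes were higher at 3 days too, where independence would give 253.5 and 264.7.

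The difference of the stroke effect between the cell types (microglia minus astrocyte) was tested in a joint fit. The cell types also differ in library kit, so that levels were not tested between them. At 4 hours Csf1 rose more in microglia (3.81) than in astrocytes (0.53, difference 3.30, SE 0.23), the glucose transporter Slc2a1 was at 1.88 and -0.29 (difference 2.17, SE 0.18). The transcription regulator Id2 was at 2.41 and -0.03 (difference 2.46), the iron transporter Slc11a2 at 1.31 and -0.13 (difference 1.45) and Clic4 at 2.16 and 0.30 (difference 1.87). At 3 days the mannose-6-phosphate receptor gene Igf2r was at 4.09 in microglia and 0.16 in astrocytes, Cspg4 at 4.04 and 0.22 (difference 3.83) and Bcar3 at 2.82 and -0.61 (difference 3.42). By contrast the kinase subunit Prkab1 was at -1.34 and 1.10 (difference -2.42) and Arhgap22 at -0.52 and 3.01. The joint fit called 1085 of 17884 genes at 4 hours (674 higher and 411 lower in microglia) and 4769 at 3 days (1844 and 2925), where the median of all genes was -0.13. Voom called 2115 at 4 hours. Of 14866 genes tested in both cell types, 353 were higher in both at 4 hours (80.5 if independent) and 1760 at 3 days (815.5 if independent). At 3 days 1507 were lower in both (771.8 if independent), the cell types sharing no control libraries. In the same astrocyte IP libraries at 3 days all 14 microglia markers (median 3.96) and all 11 monocyte markers (median 3.77) rose, and what RNA of immune cells adds to the genes higher in both or to the 2925 was not tested.

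Whole-tissue inputs gave the stroke effect in unselected brain RNA. In the astrocyte-line inputs at 3 days (3 sham and 3 stroke libraries) osteopontin (Spp1) went from 7.43 ± 0.977 to 530.9 ± 226.8 CPM (6.08, SE 0.32), Lgals3 rose by 5.86 (SE 0.29), the lysozyme Lyz2 by 4.31, C3ar1 by 4.00 and transglutaminase Tgm1 by 5.25. All 13 pan-reactive genes were higher (median 2.94), with Gfap at 3.05 (SE 0.22). Also higher were 20 of 20 cell cycle genes (median 3.18), 18 of 18 cytokine genes (median 3.72), 14 of 14 microglia markers (median 2.29) and 9 of 10 monocyte markers (median 3.19). Of the neuron markers 7 of 14 were lower (median -0.34), and Nefl, Nefm, Slc17a7 and Snap25 lost the call when single libraries were left out. The fit called 5785 of 16969 genes (3138 higher, 2647 lower). Without male sham library 182 it called 3681 and without male stroke library 305 it called 3748. Genes higher in the astrocyte IP and in the input at 3 days numbered 1951, where independence would give 781.3, although inputs and some IP libraries carry the same animal numbers.

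At 4 hours the astrocyte-line inputs had 79 genes called (75 higher, 4 lower), among them Hspa1a at 5.72 (SE 0.28) and Hspa1b at 5.58, uncertain as paralogs, Jun at 1.68 (SE 0.14), Slc15a3 at 1.903 (SE 0.19) and Hmox1 at 1.78, whose call was lost with the batch as a term. DESeq2 called 263 and voom 204, and leave-one-out counts ran from 13 without library 222 upward and were highest without library 196. In the microglia-line inputs at 4 hours (3 sham, 4 stroke) 4 genes were called, all higher: Hspa1a (5.63, SE 0.34), Atf3 (4.98, SE 0.66), Hspa1b (4.68) and the co-chaperone Dnajb1 (2.07, SE 0.26). All but Hspa1a lost the call when single libraries were left out. DESeq2 called 81 and voom 2542, and without the 5 sham inputs that lay apart 1 gene was called, with 1 sham library left at this time. At 3 days (4 sham, 3 stroke) edgeR called 0, with 4907 at an unadjusted p under 0.05. DESeq2 called 2157, voom 7033, and edgeR 3810 without male sham library 97. In the microglia-line inputs of both times 5 of 7 sham libraries lay apart from all others, on a first principal component holding 64.6% of the variance.

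**Figure D4:**
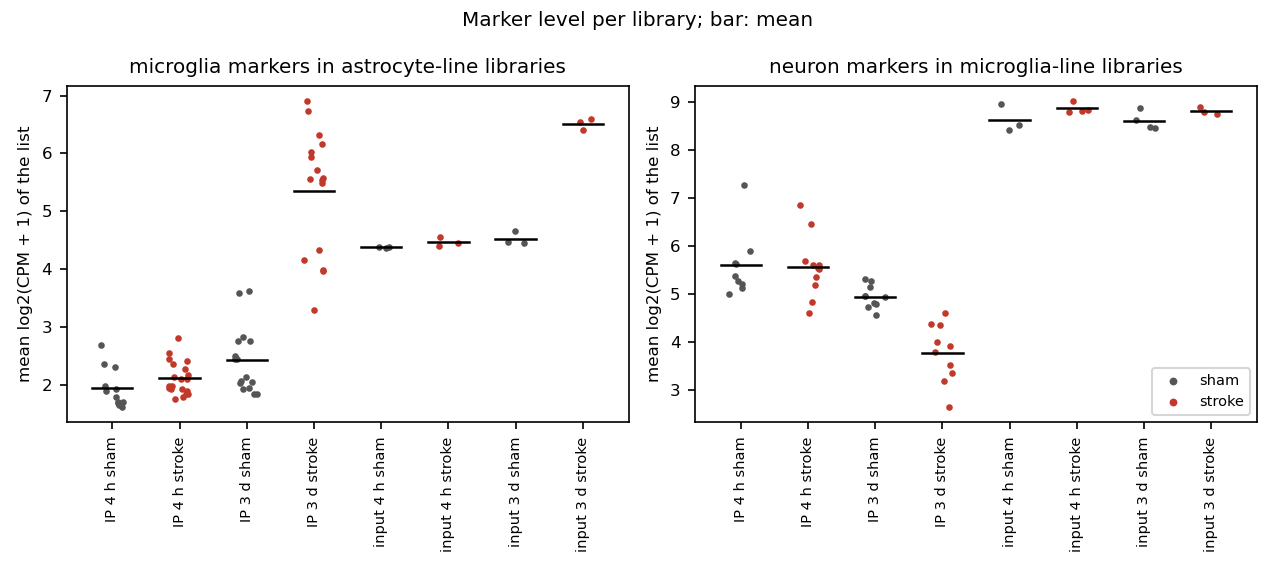
Mean log2 CPM plus 1 of the microglia markers in the astrocyte-line libraries and of the neuron markers in the microglia-line libraries, for IP and input by time and treatment. Points are libraries and the bar is the mean. Microglia markers in the astrocyte IP at 3 days average 2.43 in sham and 5.36 in stroke libraries, and neuron markers in the microglia IP 4.95 and 3.78.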

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

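The tests of whole-tissue carry-over, of less astrocyte RNA, of fewer neuron transcripts, of dilution and of a state shared by animals were chosen only after the result was seen; those of microglia RNA in a single proportion, of a difference between sham and stroke brains and of other splits were set before.

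The first pattern is the rise of microglia markers in the astrocyte IP at 3 days (median 3.96). Less astrocyte RNA in the stroke libraries would raise the markers of every other cell type, but the neuron median was -0.83 (within batches -1.38 and -0.37). The oligodendrocyte median was -0.31, with a sign that differed between the ranges (within batches -0.78 and 0.11, neither called). A constant share of whole-tissue RNA would need a median of 53.5% of the input level to give the rise (lowest 5.90%, for P2ry12), but the neuron markers in the same libraries allow a median of 3.40% (highest 9.47%, for Tubb3), 3.98 lower on the log2 scale with a spread of 1.57. RNA of microglia added in a single proportion could not be told apart. Shares of the level in microglia IP libraries had an SD of 1.29 on the log2 scale (0.252% for P2ry12 to 5.64% for Ctss). The cell types differ in library kit, which may spread such shares by gene, so the test is void. Under the rule set before, an SD of this size would have counted against a single proportion. That rule was set aside because of the kits. A change in what the pulled-down ribosomes carry, a biological candidate, and RNA of reactive microglia or infiltrating cells that differs from that of the microglia line may both remain open, and neither was tested.

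The next pattern is the fall of neuron markers in the microglia IP at 3 days (median -1.25). Fewer neuron transcripts in the tissue might account for it, but in the astrocyte-line inputs these markers fell by a median of 0.34 with a spread of 0.26 (-0.34), short of the bound of -0.62. Dilution by more microglia RNA as the whole cause would lower the markers of all other cells alike, but the oligodendrocyte median of -0.33 lay 0.91 above the neuron median, beyond the pooled SD of 0.30. Mural (-0.88), endothelial (-0.68) and astrocyte (-0.63) medians fell too, so dilution may still account for part of the fall. In the astrocyte-line inputs at 3 days the oligodendrocyte median was 0.38 beside the neuron median of -0.34. The tissue itself thus differed between these lists, which the comparison of their medians does not take into account. Dilution joined with such a change of the tissue was not tested and may remain open for the whole fall. A biological change in neuronal RNA held by microglia was not tested.

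In the last pattern, 5 of 7 microglia-line sham inputs (Input_88, Input_91, Input_92, Input_239 and Input_240) and 0 of the stroke inputs lay apart. The 5 had scores of 3.30 to 5.63 against -0.89 to 0.10 in the others. The scores used the 400 genes that differed most between these same libraries. The gap, and the 4.61 given below, are therefore raised by the choice of genes. A state of those animals shared by all their RNA would show in their IP libraries. There 4 such libraries differed from other sham IP libraries by 0.058 (SE 0.16) against 4.61 in the inputs. Markers of neurons, oligodendrocytes and astrocytes are depleted in the microglia IP. A state of those cells alone need not show there, was not tested and may remain too. A difference between sham and stroke brains would show in the astrocyte-line inputs, where it was -0.12 (SE 0.13). A difference in how these inputs were handled may remain; the labels name none, and without the 5 libraries edgeR called 1 gene at 4 hours and 5 at 3 days, with 1 sham library left at each time and the spread taken from the other groups.

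Differences between groups passed the test in 4269 genes (time, microglia), 4926 (time, astrocytes), 1085 (cell type at 4 hours), 4769 (cell type at 3 days) and 2 (sex, astrocytes at 4 hours). Among other splits of the same libraries, the real split alone reached its count (1 of 100 splits) for the stroke effect in microglia at 4 hours (2158, highest other 43) and 3 days (6515, highest other 4), in astrocytes at 4 hours (1486, highest other 477) and 3 days (8102, highest other 2401), and for time in microglia (4269, highest other 1052) and astrocytes (4926, highest other 135). The same held in 1 of 50 splits for IP against input (13964 with 0 as the highest other in microglia, 13994 with 2843 in astrocytes). It also held in 1 of 40 for cell type at 3 days (4769, highest other 17). For IP against input a share under 0.05 makes chance unlikely. For the stroke effects the other splits mix sham and stroke libraries at both times, and both times share 1 fit. A share under 0.05 there makes it unlikely that chance alone gave the stroke effect over both times. Mixing at 3 days, where more genes were called, adds to the spread at 4 hours. The low counts of the other splits therefore cannot decide on chance for 4 hours alone. For time and cell type the splits mix times or cell types within each group, which adds to the spread. Their low counts therefore cannot decide on chance for these differences. Chance was not excluded for the cell type difference at 4 hours, where 2 of 40 splits reached 1085 and the highest other gave 7682, nor for the sex difference in astrocytes at 4 hours, where 13 of 100 splits reached 2 (highest other 2549). In the microglia-line inputs at 4 hours 2 of 35 splits reached 4 (highest other 82), so chance was not excluded there either. An edgeR count of 0 is reached by every split, so the splits test nothing for sex in microglia at 4 hours (100 of 100, highest other 582) and 3 days (100 of 100, highest other 17), for sex in astrocytes at 3 days (100 of 100, highest other 2096) and for the microglia-line inputs at 3 days (35 of 35, highest other 4107). Why some splits call several times the real count was not tested. For the astrocyte-line inputs the 10 splits are too few for a share under 0.05: the real values were 79 (highest other 2) and 5785 (highest other 0), each reached by 1 split.

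Single libraries lay far from their group in 34 of 368 tests. Each test took 1 measure (total count, a marker list or a gene of the largest rises or falls) in 1 group. Chance gives about 5% (1 in 20) in independent tests, but these tests share libraries, so 34 cannot be set against that share. The number given is the gap to the nearest library as a share of the group's range. In the astrocyte IP, female sham 3 days no. 202 was highest for monocyte markers (0.606), Arg1 (0.604), Adam8 (0.688) and Msr1 (0.711), no. 317 for ependymal markers (0.535) and no. 530 for Coq8a (0.535). Female sham 4 hours no. 499 was highest for neuron (0.893) and lymphocyte markers (0.880) and lowest for Galnt18 (0.854). Male sham 4 hours no. 506 was highest for Hspa1a (0.688), Hspa1b (0.584) and Chac1 (0.586), and no. 363 for fibroblast markers (0.684). Among stroke libraries, no. 159 (mural markers, 0.643), no. 198 (lymphocyte markers, 0.546), no. 338 (Chac1, 0.472) and no. 481 (neutrophil markers, 0.741) were highest, and no. 527 had the lowest total (0.564).

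In the microglia IP, female sham 3 days no. 100 was highest for endothelial (0.860) and mural markers (0.714), IP_219 lowest for fibroblast markers (0.759) and no. 88 highest for Prss46 (a gap as large as the range, 0.452 as log2 of CPM plus 1 against a median of 0 in the others). Male sham 3 days no. 91 had the lowest total (0.751) and the highest Ddit4 (0.804), and IP_253 the highest Prss46 (0.937). Male sham 4 hours IP_153 was lowest for microglia markers (0.722) and Inka1 (0.724) and highest for oligodendrocyte markers (0.893). Female sham 4 hours IP_257 was lowest for microglia markers (0.911), and IP_239 lowest for Gdf15 (0.974) and Ccl4 (0.918). Male stroke 4 hours IP_251 was highest for astrocyte markers (0.728) and female stroke 3 days IP_241 for ependymal markers (0.825).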

How the results depend on the processing

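Values within library-number ranges, without doubted libraries and without the 5 inputs that lay apart come from tests chosen only after the result was seen. The counts of the stroke effect and time difference in IP libraries and of IP against input kept within 1.5 times their value with DESeq2 size factors, its Wald test, no low-count filter and without low-depth or doubted libraries (the last 2382 and 6592 in microglia, 1528 and 7859 in astrocytes). Of 22309 pairs of a named gene and an alternative, 21707 gave the same call, 274 lost it, 328 gained it and 0 reversed. Among the 21707, 306 changed sign but were called in neither fit. Many pairs come from leaving out a single library, at times of the other time point, so agreement was partly fixed beforehand. What depth and group size limit was not tested apart, and the simulated 4-fold changes recovered were 84.9% in astrocyte-line and 48.4% in microglia-line inputs. Where a value below moved, the cause was not tested.

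Voom with sample weights called 3654 (stroke effect, microglia 4 hours), 4963 (astrocytes 4 hours), 6504 and 8523 (time, microglia and astrocytes) and 2115 (cell type, 4 hours). The neuron covariate gave 3195 in microglia at 3 days, where it turned the marker list medians to 0.33 (astrocyte), 0.11 (neuron) and 0.56 (oligodendrocyte); the covariate is built from the neuron list itself. In astrocytes the higher and lower numbers gave 518 and 434 at 4 hours, and the lower numbers 1860 for time. Sex differences numbered 2 with DESeq2 in microglia at 4 hours, 17 with DESeq2 and 34 with voom at 3 days, and 3 and 89 in astrocytes at 3 days; in astrocytes at 4 hours DESeq2 called 1, and voom, only this time point, the higher numbers and the lower numbers each called 0 (160 at an unadjusted p under 0.05 by edgeR in all libraries). Of 56 list calls, 18 held with an estimated correlation. Fry called 63 lists, but lost 6 of the 18 calls in astrocytes at 4 hours. In microglia at 3 days the neuron covariate ended 3 of 11 list calls (neuron, complement and phagocytosis, unfolded protein response) and added 4 (microglia down, and astrocyte, oligodendrocyte and oligodendrocyte precursor up).

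In the microglia-line inputs DESeq2, no filter, voom and leaving out the 5 libraries gave 81, 655, 2542 and 1 at 4 hours, and 2157, 3024, 7033 and 5 at 3 days. The counts of 1 and 5 rest on 1 sham library at each time, with the spread taken from the other groups. In the astrocyte-line inputs at 4 hours DESeq2 gave 263, no filter 637 and voom 204.

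Leaving out each library of small groups in turn gave 13748 to 13855 (IP, microglia) and 13864 to 13952 (IP, astrocytes). Stroke effects ran from 1711 to 2396 and from 5893 to 6905 in microglia at 4 hours and 3 days, and from 918 (without female sham 491) to 1989 and from 8102 to 8169 in astrocytes. Time differences ran from 3736 to 5019 and from 4185 to 5480. Sex differences were 0 to 0 in microglia at 4 hours, 0 to 6 at 3 days (2 without IP_252 and 6 without IP_253), 0 to 4 in astrocytes at 4 hours (0 without no. 478, 4 without no. 491 or no. 499) and 0 to 0 at 3 days. In astrocyte IP libraries only the 4 female sham libraries of 4 hours were left out, so the ranges at 3 days say nothing about stability there. Microglia-line inputs ran from 2 to 419 at 4 hours (2 without Input_240, 7 without Input_143, 12 without Input_97, 419 without Input_109) and from 0 to 3810 at 3 days (2 without Input_88, 2014 without Input_109, 3810 without Input_97). Astrocyte-line inputs were 13, 14, 20, 25 and 37 at 4 hours without no. 222, 363, 223, 536 and 331, and 1.5e2 (to 2 digits), the highest, without no. 196. They ran from 3681 to 6324 at 3 days (3681 without no. 182, 3748 without no. 305).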

Other observations

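All values in this part were chosen after the result was seen. In the astrocyte-line inputs at 3 days, endothelial and connective tissue genes were higher beside the immune genes: 7 of 10 endothelial markers (median 0.70), with the tight junction gene Cldn5 going from 24.5 ± 9.21 to 64.3 ± 26.7 CPM in 3 libraries each (1.35, SE 0.27) and Pecam1 rising by 1.23 (SE 0.20), and 5 of 6 fibroblast markers (median 1.71), with the collagen genes Col3a1 rising by 2.71 (SE 0.43) and Col1a1 by 1.51 (SE 0.33). Mural cell markers were higher in 3 of 8 (median 0.34), and the vessel markers Esam, Tek and Acta2 lost the call when single libraries were left out. Oligodendrocyte precursor markers were higher in 4 of 6 (median 0.43), among them Gpr17 by 0.54 (SE 0.13), while Cspg4 and Pdgfra lost the call when single libraries were left out.

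The astrocyte genes Aqp4, coding for a water channel, and S100b were higher in these inputs by 0.83 (SE 0.15) and 0.72 (SE 0.13), beside a median of 0.17 over 13 astrocyte markers.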
